A study of Homo sapiens with 6 samples.

How the data were processed

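RNA-seq libraries of the human melanoma cell line A375 were analysed in 2 groups of 3, untreated cells and cells treated for 24 h with 3 µM fluvastatin. Total RNA was extracted with a column kit and libraries followed Illumina's own protocols, per the labels' protocols. Per the submitters' processing notes, the authors used STAR, Cufflinks, Cuffdiff and the hg38 genome, and the deposited table holds 1 value per gene and library. The header names no unit, and the values were taken as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) as the authors' Cufflinks tools give it, since they are not whole and their sums per library lay between 686133.2 and 729564.0. Tool versions, the annotation release, the strand setting of the counting and any rescaling between libraries were not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical gene copies may share reads.

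The table held 29790 genes, of which 29542 identifiers matched GENCODE release 29 when the version was ignored, and 54 symbols stood on more than 1 line and were kept apart by identifier. Gene types, coordinates and transcript lengths came from that annotation on GRCh38. No gene was at 0 in all 6 libraries. The RNA gene RMRP, chosen after its values were seen, took 8.96% to 11.16% of each library's FPKM sum. At most 2 genes had identical values above 0 in any pair of libraries, so no library was a copy of another. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.9704 to 0.9794 within groups and 0.9495 to 0.9573 between them.

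FPKM values carry no counts, so depth was estimated from the steps between low values, since 1 fragment is worth a fixed amount for a gene in a library. Of 11289 genes at 0 in at least 1 library, 78.0% held whole multiples of a common unit, within 0.06 of the smallest value. The smallest value could be 1 to 6 units, and the fewest units that met the tolerance were used. Fragment numbers per gene are therefore the smallest that the values allow. Genes above 0 in only 1 library met the tolerance in any case. The relative depths were 1.00, 1.19 and 0.96 for control replicates 0, 1 and 2 and 1.27, 1.50 and 1.39 for fluvastatin replicates 0, 1 and 2, with control replicate 0 as the reference. On 6 simulated libraries the method returned the log2 relative depth with a largest error of 0.001 over 29790 genes. The simulated values had 1 length per gene and no rescaling, and 100% of their genes with a 0 were resolved, against 78.0% here. The error need therefore not hold for the real values. Absolute fragment numbers, which also rest on annotated transcripts of at least 1000 nt, are approximate. Deeper libraries carry less counting error, and here those were the treated ones.

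Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, no replicate block), two-sided. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen. Group means, SDs and folds are on the FPKM scale, and log2 fold changes with their standard errors are on the log2(FPKM + 1) scale. Of 34 gene lists written from textbook knowledge, the 30 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with all tested genes as background and adjustment over the 30 lists. An estimated correlation and fry, which tests the members alone, were run beside it. Of some lists the members are shared, such as EGR1, ATF3, JUN, HMOX1, NT5E and COL1A1. The fit was tested on simulated data with the real genes' means and spreads over 14344 genes. It recovered 16%, 84%, 96% and 100% of 50 genes each changed by log2 0.5, 1, 2 and 3, with 8 of 163 calls on unchanged genes, and called 0 of 30 lists of unchanged genes. The simulated genes varied independently of each other. The 0 of 30 therefore does not cover lists whose members vary together, such as the mitotic genes with an estimated correlation of 0.368. In that simulation changes of log2 0.5 were often missed. The real data gave 3971 calls, far more than the 163 simulated ones, which makes the adjusted threshold less strict. The 16% need therefore not hold for the real data.

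Named genes followed a rule, and it and the samples' groups, the main test, the 34 lists and most alternatives were set before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and a fixed list of statin, YAP and melanoma genes. Some named genes and 2 of the lists are not reported here. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, scaling by a trimmed mean of M-values, quantile normalization, eBayes with trend and robust on, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. The trimmed mean scaling was an own implementation of the published procedure. Tests of genes of at least 300 nt alone, of protein-coding genes alone and with the log2 relative depth as a covariate were added after the data were seen. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main comparison.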

Results

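RNA was sequenced from A375, an established human melanoma cell line, either left untreated or exposed for 24 h to 3 µM fluvastatin. Fluvastatin is a statin, a drug that blocks the mevalonate pathway, which supplies cholesterol and the isoprenoid lipids that anchor many signalling proteins in membranes. The series held 3 control libraries and 3 fluvastatin libraries, numbered 0, 1 and 2 in each group, and the comparison asked which transcripts differ after the drug. Values were taken as FPKM per gene, fragments per kilobase of transcript scaled to the number of mapped fragments. The steps between low values gave depths of 1.19 and 0.96 for control replicates 1 and 2 and of 1.27, 1.5 and 1.39 for fluvastatin replicates 0, 1 and 2, relative to 1 for control replicate 0. Every fluvastatin library was thus deeper than every control, and depth and treatment could not be separated. The labels describe triplicates without saying that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

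Fluvastatin was followed by a large rise of RHOB, a small GTPase of endosomes and the actin cytoskeleton, from 9.71 ± 1.14 FPKM (SD, n = 3) to 374.7 ± 28.5 FPKM (SD, n = 3), which is 38.6-fold. KLF2, a zinc-finger transcription factor known as a statin-responsive gene of endothelial cells, rose 16.9-fold, from 9.96 ± 0.717 to 167.9 ± 21.9 FPKM. HAS2, which makes hyaluronan, rose 20.6-fold, and IL1B, the cytokine interleukin-1 beta, rose 7.32-fold. In the other direction, CYR61, a secreted matricellular protein and a YAP/TEAD target, fell 3.91-fold, from 125.0 ± 4.43 to 32.0 ± 2.21 FPKM. THBS1, which encodes the matrix glycoprotein thrombospondin-1, fell 4.99-fold, from 485.6 ± 70.8 to 97.3 ± 20.9 FPKM.

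Of 14344 genes tested with limma on log2(FPKM + 1), 3971 changed at a Benjamini-Hochberg adjusted p below 0.05, with 2017 that rose and 1954 that fell. Of these, 386 rose and 113 fell at least 2-fold on that scale, which understates the change of low genes. In 6425 genes (44.8%) all 3 fluvastatin libraries lay on the same side of all 3 controls, where chance gives 10%. Adding the estimated depth of each library as a covariate, a setting chosen after the data were seen, left 79 genes past the threshold (64 higher, 15 lower). Leaving out fluvastatin replicate 0, 1 or 2 left 2277, 2524 and 2561 genes.

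RHOB (ENSG00000143878.9) lies on chromosome 2 at positions 20447074 to 20449445 of GRCh38, plus strand, and its log2 fold change was 5.14 ± 0.11 (SE; adjusted p = 6.70e-06). KLF2 (ENSG00000127528.5; chromosome 19, 16324817 to 16327874, plus strand) had a log2 fold change of 3.94 ± 0.12 (adjusted p = 3.67e-05). HAS2 (chromosome 8, 121612116 to 121641390, minus strand) went from 2.45 ± 0.463 to 50.4 ± 7.23 FPKM, with adjusted p = 7.23e-05. LYPD3, which encodes a membrane-anchored protein of the Ly6 family, rose 35.7-fold from 0.532 ± 0.417 to 19.03 ± 2.72 FPKM. The LYPD3 fold rested on low controls and was 65.05 without control replicate 1, and its log2 fold change ranged from 2.99 to 5.10 over all settings. MYO15B, an unconventional myosin gene, rose 12.7-fold. CYR61 (ENSG00000142871.16; chromosome 1, 85580761 to 85583962, plus strand) had a log2 fold change of -1.94 ± 0.09 (adjusted p = 1.28e-04). IL7R, the receptor chain for interleukin-7, fell 4.73-fold, and LIMCH1, an actin-associated protein, fell 3.59-fold. CTD-2033D15.2, a sense intronic RNA lying within THBS1 on the same strand, fell from 7.37 ± 0.622 to 1.34 ± 0.353 FPKM, and its reads cannot be told apart from those of THBS1. The 12 largest rises also held 6 genes under 300 nt listed at 0 in all 3 controls. By the smallest numbers that the values allow, each rested on 1 to 4 fragments in a fluvastatin library. The 12 largest falls held 5 short RNA genes. PTPRD, a receptor-type tyrosine phosphatase gene (chromosome 9, 8314246 to 10612723, minus strand), was at 49.0, 42.5 and 46.6 FPKM in control replicates 0, 1 and 2 and was listed at 0 in each of the 3 fluvastatin libraries. No feature within that locus was above 0 in any fluvastatin library, and an exact 0 in these files can be a failed estimate.

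**Figure D1:**
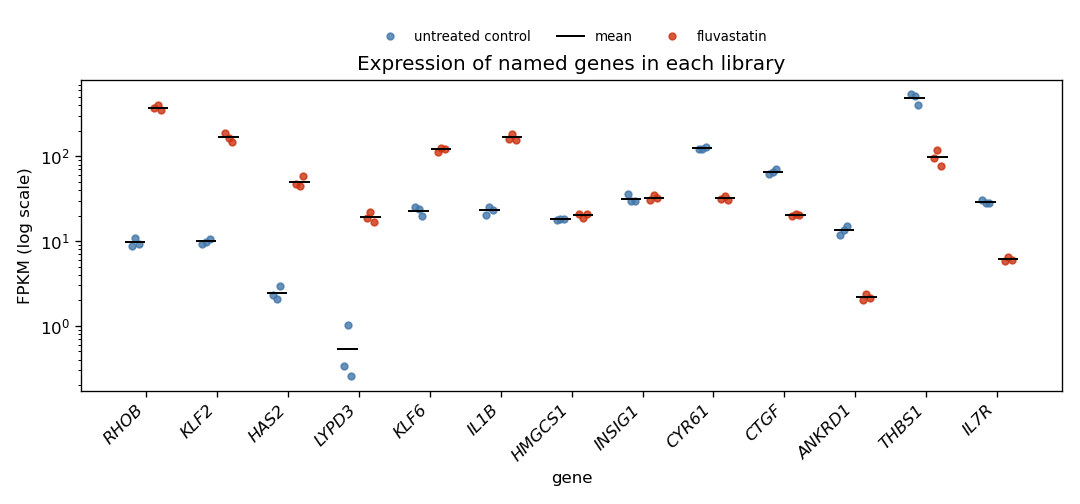
Expression of 13 named genes in each library, with genes along the horizontal axis and FPKM on a logarithmic vertical axis, blue points for the 3 untreated controls, red points for the 3 fluvastatin libraries and short lines for the group means. RHOB went from 9.71 to 374.7 FPKM and CYR61 from 125.0 to 32.0 FPKM, while INSIG1 was at 31.8 and 32.7 FPKM.

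Genes of the sterol pathway that the drug blocks changed in few cases and in both directions. INSIG1, which retains the SREBP activator in the endoplasmic reticulum, was at 31.8 ± 3.68 and 32.7 ± 1.93 FPKM (adjusted p = 0.806). HMGCS1, an early enzyme of the mevalonate pathway, was at 18.1 ± 0.289 and 20.2 ± 1.197 FPKM (adjusted p = 0.234). SREBF2, the transcription factor of sterol genes, was at 43.5 ± 3.38 and 54.3 ± 3.96 FPKM (adjusted p = 0.0599) and passed in 4 alternatives, at a mean of at least 5 FPKM (0.0407), with quantile normalization (0.0441), with trend and robust on (0.0315) and among protein-coding genes alone (0.0406), over a range of 0.0315 to 0.627.

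Among 20 cholesterol synthesis enzymes tested, 2 rose, 4 fell and 14 did not pass, with the same counts adjusted over the list alone, and camera gave the list adjusted p = 0.899. LSS rose 1.52-fold, whereas FDFT1 fell 1.38-fold, ACAT2 1.38-fold and DHCR7 1.44-fold. The LSS call was lost without fluvastatin replicate 0 (0.0516, over a range of 0.00665 to 0.322). The FDFT1 call was lost without control replicate 0 (0.0643) or 1 (0.0650) or fluvastatin replicate 0 (0.0632) or 1 (0.0526), over a range of 0.00806 to 0.200. The ACAT2 call was lost without control replicate 1 (0.0738) or 2 (0.0561) or fluvastatin replicate 0 (0.0735) or 2 (0.0670), over a range of 0.0119 to 0.166, and the DHCR7 call without control replicate 1 (0.0794) or 2 (0.06) or fluvastatin replicate 0 (0.0821) or 1 (0.0682), over a range of 0.0133 to 0.158. In the group of sterol uptake and SREBP feedback genes, 2 of 10 rose, 2 fell and 6 did not pass, against 3 and 2 adjusted over the list alone. The median log2 fold change was 0.01, the mean -0.01 and the camera direction up (adjusted p = 0.7995). NPC1, a lysosomal cholesterol exporter, rose 1.39-fold, while TMEM97, a regulator of NPC1 stability, fell 2.18-fold and SCARB1, a lipoprotein receptor, fell 1.64-fold. Of 9 LXR target genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.899), with SMPDL3A up 2.07-fold, MYLIP down 1.66-fold and the cholesterol exporter ABCA1 at 3.83 ± 0.472 and 3.55 ± 0.198 FPKM. Fatty acid synthesis enzymes shifted down as a group, with 4 of 13 that fell and none that rose under either adjustment, the median at -0.21 and camera adjusted p = 0.0172. That group gave adjusted p = 0.357 with an estimated correlation and 0.0553 at a mean of at least 5 FPKM, over a range of 6.33e-04 to 0.482. FADS2 fell 1.43-fold and ACACA, the first committed enzyme, fell 1.45-fold. Of 17 genes of the isoprenoid branch and of prenyl transfer, DHDDS and RABGGTA rose 1.36-fold and 1.35-fold and 15 did not pass, whereas 0 passed adjusted over the list alone (camera adjusted p = 0.8735). DHDDS lost its call without fluvastatin replicate 0 (0.0628) or 2 (0.0645), over a range of 0.0105 to 0.435, and RABGGTA without control replicate 1 (0.115) or 2 (0.0985) or fluvastatin replicate 0 (0.118) or 1 (0.120), over a range of 0.0243 to 0.424.

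Krüppel-like factors and endothelial-type statin targets rose in 8 of 10 members and in 9 of 10 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 5.99e-06; adjusted p = 0.0968 with an estimated correlation). KLF6 rose 5.28-fold from 22.9 ± 2.82 to 120.8 ± 6.56 FPKM, KLF9 3.11-fold and KLF3 2.65-fold. HMOX1, the haem-degrading enzyme counted both here and among the NRF2 targets, rose 1.88-fold.

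YAP/TEAD target genes, which respond to Hippo signalling and to actin tension, mostly fell. Of 21 tested, 12 fell, 4 rose and 5 did not pass, also adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.00928; adjusted p = 0.169 with an estimated correlation). Besides CYR61, CTGF fell 3.26-fold from 65.8 ± 4.35 to 20.2 ± 0.526 FPKM and ANKRD1, a nuclear co-factor, fell 6.20-fold from 13.5 ± 1.71 to 2.18 ± 0.183 FPKM. Against that direction IGFBP3, which binds insulin-like growth factors, rose 2.85-fold and NT5E, an ectoenzyme that makes adenosine, rose 1.84-fold. AXL, a receptor tyrosine kinase in this list and in that of the dedifferentiated state, was at 335.3 ± 12.6 and 317.6 ± 11.2 FPKM (adjusted p = 0.524). Actin cytoskeleton and SRF target genes were mixed, with 6 of 22 that rose, 5 that fell and 11 that did not pass, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.713). CNN2, a calponin, fell 1.94-fold and the cytoplasmic actin ACTG1 1.55-fold, while FHL2 rose 1.54-fold.

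Genes of DNA replication fell almost without exception. Of 25 S-phase genes, 23 fell, 0 rose and 2 did not pass, 24 fell adjusted over the list alone, and the median log2 fold change was -0.84 (camera adjusted p = 7.78e-13; adjusted p = 0.127 with an estimated correlation). UNG, a uracil-removing repair enzyme, fell 2.32-fold from 62.3 ± 0.0684 to 26.8 ± 1.09 FPKM, and the replicative helicase subunits MCM3, MCM4 and MCM6 fell 2.10-fold, 1.93-fold and 1.94-fold. Mitotic genes fell in 22 of 25 cases, 23 adjusted over the list alone, with 1 that rose, 2 that did not pass and a median of -0.57 (camera adjusted p = 3.55e-09; adjusted p = 0.328 with an estimated correlation). The cyclin CCNA2 fell 1.78-fold and the spindle kinases AURKB, BUB1 and AURKA fell 1.58-fold, 1.66-fold and 1.65-fold. The member that rose, UBE2C, an E2 enzyme of the anaphase-promoting complex chosen after its values were seen, increased 1.34-fold. CCND1, the cyclin of early G1, was at 255.1 ± 35.6 and 249.8 ± 38.9 FPKM (adjusted p = 0.900).

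CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.47-fold from 68.4 ± 8.67 to 169.0 ± 20.6 FPKM (log2 fold change 1.29 ± 0.14, adjusted p = 0.00162). Of 18 p53 target genes tested, 5 rose, 1 fell and 12 did not pass, also adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0170; adjusted p = 0.459 with an estimated correlation). BBC3, a pro-apoptotic BH3-only gene, rose 3.73-fold, TP53INP1 2.49-fold and ZMAT3 1.65-fold. Without fluvastatin replicate 1 the list gave 0.0933, over a range of 0.00331 to 0.459. In the BCL2 family 2 of 11 rose, 1 fell and 8 did not pass, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.340), with the BH3-only gene BIK up 2.62-fold from 9.03 ± 1.81 to 23.7 ± 3.15 FPKM.

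Stress-response groups rose in part. Of 17 genes of the unfolded protein response, 7 rose and 0 fell, 8 rose adjusted over the list alone, and the median was 0.37 (camera adjusted p = 0.00615; adjusted p = 0.169 with an estimated correlation). The endoplasmic reticulum chaperone HSPA5 rose 1.66-fold, its co-chaperone DNAJB9 3.07-fold and HERPUD1, of ER-associated degradation, 2.75-fold. The ATF4 and amino acid response list split, with 4 of 19 that rose and 4 that fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.713). ATF3, a stress-induced transcription factor, rose 2.77-fold and PPP1R15A, a phosphatase subunit that restores translation, 2.35-fold, whereas the serine synthesis enzymes PHGDH and PSAT1 fell 1.53-fold and 1.90-fold. The call for PSAT1 was lost without fluvastatin replicate 1 (0.0523, over a range of 0.00530 to 0.398). NRF2 target genes rose in 6 of 14 cases and fell in 1, or 7 and 2 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.0473; adjusted p = 0.513 with an estimated correlation). The ferritin heavy chain FTH1 rose 1.69-fold, TXNRD1, which reduces thioredoxin, 1.62-fold and OSGIN1 3.81-fold, or 6.09-fold without control replicate 1, with a log2 fold change of 0.61 to 1.96 over all settings. Lysosome and autophagy genes rose in 9 of 18 cases and fell in 0, or 12 and 2 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 7.33e-04; adjusted p = 0.220 with an estimated correlation). The autophagy-initiating kinase ULK1 rose 2.64-fold, WIPI1 2.17-fold, MAP1LC3B 1.96-fold and GABARAPL1 2.33-fold. Of 15 glycolysis and hypoxia genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.590), with NDRG1 up 6.38-fold from 27.5 ± 5.75 to 175.4 ± 12.55 FPKM and PFKFB4 up 1.79-fold.

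NF-kB targets and cytokines rose in 13 of 17 cases, fell in 2 and did not pass in 2, also adjusted over the list alone, with a median of 0.77 (camera adjusted p = 5.99e-06; adjusted p = 0.0968 with an estimated correlation). IL1B rose from 22.996 ± 2.36 to 168.4 ± 15.3 FPKM, the NF-kB inhibitors TNFAIP3 and NFKBIA rose 3.88-fold and 1.95-fold, and BIRC3, an inhibitor of apoptosis, rose 3.49-fold. IL6 fell from 1.30 ± 0.258 to 0.505 ± 0.182 FPKM, a call lost without fluvastatin replicate 1 (0.0505, over a range of 0.00617 to 0.460). Interferon-stimulated genes went both ways, with 3 of 19 that rose, 7 that fell and 9 that did not pass, also adjusted over the list alone. Their median log2 fold change was 0.08, the mean -0.03 and the camera direction down (adjusted p = 0.713). The exonuclease ISG20 rose 3.03-fold, and IFI44, IFI44L and the RNA sensor OAS3 fell 2.16-fold, 2.34-fold and 1.54-fold. Antigen presentation genes rose in 4 of 17 cases and fell in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.109), with HLA-DRB1 at 0.493 ± 0.294 and then 1.64 ± 0.238 FPKM, 3.33-fold higher or 5.07-fold without control replicate 1. Among 12 immune checkpoint and NK-cell ligand genes 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.673). CD274, which encodes the T-cell inhibitory ligand PD-L1, fell 2.25-fold from 19.8 ± 3.57 to 8.80 ± 1.09 FPKM (log2 fold change -1.08 ± 0.15, adjusted p = 0.00420), while CD276 rose 1.49-fold.

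Of the melanocyte differentiation genes 7 were expressed highly enough to test, and 1 rose, 1 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.723). SOX10, a neural crest transcription factor, rose 3.09-fold from 23.3 ± 2.99 to 72.0 ± 4.33 FPKM (adjusted p = 4.66e-04), and CDK2, also a cell cycle kinase, fell 1.63-fold. MITF, the lineage transcription factor, was at 7.18 ± 0.556 and 6.68 ± 0.505 FPKM (adjusted p = 0.529). Genes of the dedifferentiated state rose in 5 of 18 cases and fell in 2, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.713), with NGFR, a neural crest receptor, up 1.54-fold and SOX9 down 1.74-fold. Genes of MAPK pathway output rose in 8 of 19 cases, fell in 2 and did not pass in 9, also adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.0473, up; adjusted p = 0.597 with an estimated correlation). SPRY2, DUSP5 and DUSP4, feedback inhibitors of ERK signalling, rose 2.43-fold, 1.90-fold and 1.76-fold, and EGR1, an immediate early gene, rose 3.05-fold. Mesenchymal and matrix genes rose in 10 of 23 cases, fell in 6 and did not pass in 7, or 12 and 6 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0473, up; adjusted p = 0.690 with an estimated correlation). MMP1, a collagenase, rose 12.8-fold from 0.517 ± 0.161 to 6.59 ± 0.809 FPKM, MMP14 2.14-fold and COL6A1 2.02-fold, against the fall of THBS1. The NRF2, MAPK and mesenchymal calls were each lost in at least 9 alternatives, among them a pseudocount of 0.1 (0.0553, 0.0530 and 0.0530), and the block by replicate number (0.0603 for each). The NRF2 list was also lost without control replicate 2 (0.114) or fluvastatin replicate 1 (0.0761), over a range of 0.00865 to 0.513. The MAPK list was lost without control replicate 0 (0.0872) or 2 (0.0502) or fluvastatin replicate 1 (0.0902), over a range of 0.00536 to 0.597, and the mesenchymal list without control replicate 2 (0.139) or fluvastatin replicate 0 (0.196), 1 (0.328) or 2 (0.104), over a range of 0.0166 to 0.835.

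Early stress-response genes, a list fixed as a sign of handling, rose with the MAPK and NF-kB groups, in 6 of 10 cases with 0 that fell, also adjusted over the list alone, and a median of 0.41 (camera adjusted p = 0.00231; adjusted p = 0.400 with an estimated correlation). JUN rose 2.34-fold and JUNB 1.97-fold, and EGR1 and ATF3 of this list also belong to the MAPK and ATF4 lists. The 13 mitochondrially encoded mRNAs had 0 members past the threshold under either adjustment and a median of 0.34 (camera adjusted p = 0.146), and the list passed without control replicate 2 (0.00747), without fluvastatin replicate 1 (0.0151) and with the depth covariate (2.14e-05), over a range of 2.14e-05 to 0.872. MT-CO2 was at 541.4 ± 140.3 and 858.2 ± 176.2 FPKM (adjusted p = 0.0679). It passed without control replicate 2 (0.0265), without fluvastatin replicate 1 (0.0498) and among protein-coding genes alone (0.0342), over a range of 0.0265 to 0.178. Of 25 ribosomal protein genes 3 rose, also adjusted over the list alone, with RPL11 up 1.38-fold and a median of 0.01 (camera adjusted p = 0.604).

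Markers of other cell types were low or mixed. Of 4 keratinocyte and epithelial markers tested, CLDN4 rose 7.97-fold from 2.01 ± 0.256 to 16.003 ± 1.06 FPKM and KRT14 rose 7.23-fold from 0.691 ± 0.0936 to 4.99 ± 0.923 FPKM, whereas KRT10 was at 52.3 ± 13.3 and 65.5 ± 1.31 FPKM and KRT7 at 77.5 ± 5.17 and 73.9 ± 10.5 FPKM. The only fibroblast marker tested, COL1A1, which is also in the mesenchymal list, fell 1.87-fold, a call lost without control replicate 1 (0.0520), fluvastatin replicate 0 (0.0558) or fluvastatin replicate 2 (0.0566), over a range of 0.00640 to 0.111. Of the endothelial markers KDR alone was tested and rose from 0.293 ± 0.0297 to 1.34 ± 0.165 FPKM. The leukocyte markers CD68 and LYZ rose from 27.4 ± 2.57 to 43.2 ± 2.18 FPKM and from 0.893 ± 0.336 to 2.29 ± 0.156 FPKM.

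**Figure D2:**
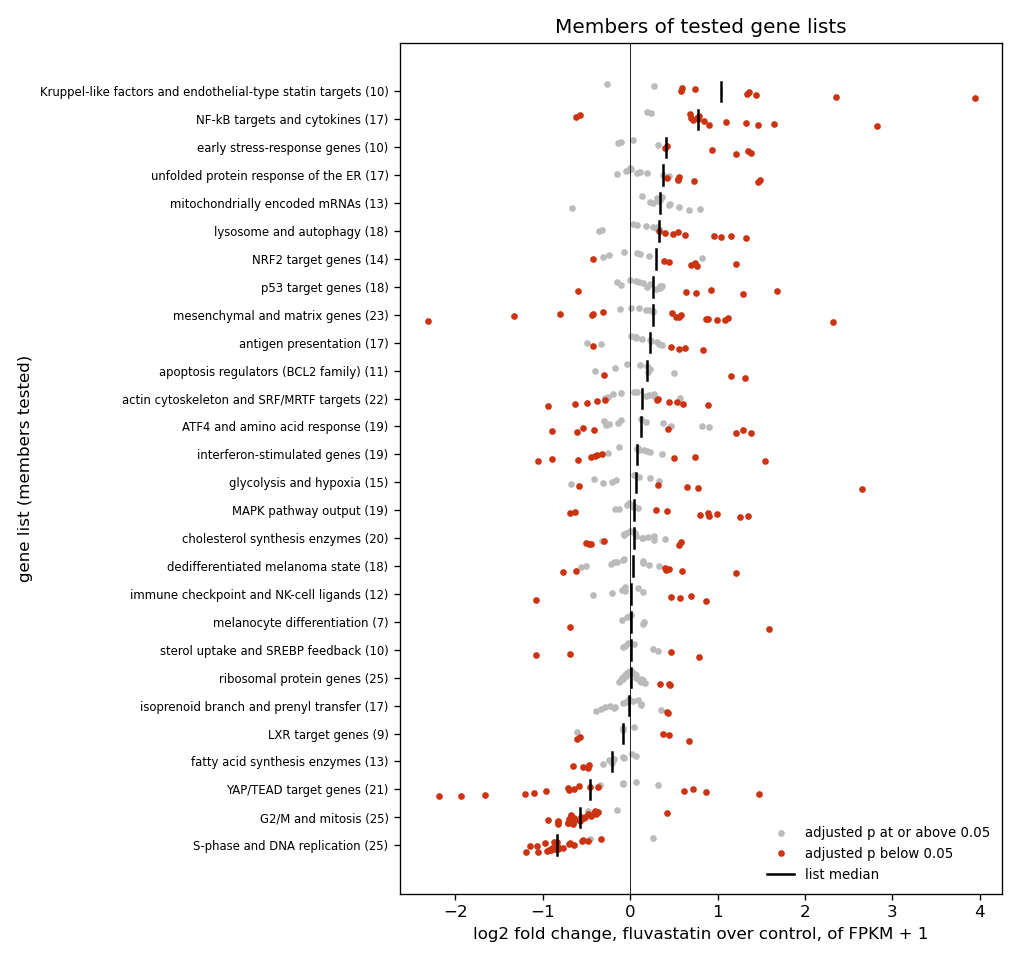
Log2 fold change of FPKM + 1, fluvastatin over control, for each tested member of the gene lists shown, with the number tested in parentheses. Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians, from -0.84 for S-phase genes to 1.04 for Krüppel-like factors.

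Of the 30 lists tested, 14 passed camera with its preset correlation (10 higher, 4 lower). With an estimated correlation 0 passed in limma, the lowest adjusted p being 0.0968, while fry, which asks whether the members themselves moved 1 way, passed 15 lists and its mixed test 29. With the depth covariate 9 lists passed.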

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

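The tests with genes of at least 300 nt, with protein-coding genes and with the depth covariate were chosen after the result was seen. The count of 3971 changed genes stayed within 1.5 times under 9 other settings, from 3154 with the replicate block to 4326 with trend and robust on, and 499 genes also had an absolute log2 fold change of at least 1. With the depth covariate 79 genes passed, 75 of them among the 3971, as did 9 lists (14 in the main test) and 22 of the 152 named genes (132 in the main test). Depth and treatment go together in these libraries, which leaves the covariate little to separate, and the lost calls do not tell an effect of depth from the loss of power. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.0968. That correlation was -0.049 for the Krüppel-like list, -0.039 for NF-kB targets, -0.027 for YAP/TEAD targets and 0.009 for the unfolded protein response. These lie below the preset 0.01, which argues against members that vary together as the cause of the lost calls of these lists. For other lists it was above the preset, such as 0.152 for S-phase genes, and the cause was not tested. Leaving out 1 library left 2277 to 3483 genes, 11 to 14 lists and 101 to 126 named genes. The gene counts were 2277, 2524 and 2561 without fluvastatin replicate 0, 1 and 2, which have fewer samples to test on. No call reversed in any setting run, and the median log2 fold change of all tested genes stayed between -0.027 and 0.008. Of the 30 lists, 7 changed their call in a setting other than the depth covariate and the estimated correlation, as did 30 named genes in a setting other than the depth covariate, and the cause was not tested. The log2 fold change ranged over all settings from 4.84 to 5.26 for RHOB, from 3.84 to 4.11 for KLF2 and from -1.99 to -1.90 for CYR61, all called throughout. The replicate block left 3154 genes, 11 lists and 123 named genes past the threshold, but same-numbered libraries deviated together with correlations of only 0.00, 0.08 and 0.08, and fluvastatin replicate 0 correlated best with control replicate 2 (0.06), so the numbers were not read as pairs. The estimated depth limits genes resting on a few fragments, in which 1 fragment more or less changes the value by a large part.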

Other observations

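The tests of the 4 further gene lists were set up after some of their genes had been seen among the changed ones, and those genes were left out of the lists, while all tests on the PTPRD locus were chosen after the result was seen, the whole-chromosome test after the window test. The adjustment over 4 lists is milder than that over the 30 fixed lists, of which 0 passed with an estimated correlation. A list that passes here therefore need not have shifted more clearly than those. Genes that hold epithelial cells together rose in a group, with 12 of 18 that rose, 3 that fell and a median log2 fold change of 0.81 (camera adjusted p = 3.04e-05 over the 4 lists; adjusted p = 0.0358 with an estimated correlation). DSP, the desmosomal plaque protein desmoplakin, rose from 1.67 ± 0.0405 to 6.96 ± 0.493 FPKM, LAMB3, a laminin chain of basement membranes, from 41.2 to 93.2 FPKM and ITGA6, a laminin-binding integrin, from 163.8 to 288.2 FPKM. Of the 3 keratins in this list, KRT80 and KRT18 fell, with log2 fold changes of -0.53 and -0.34, and KRT8 rose from 63.1 to 91.5 FPKM (log2 fold change 0.53). Of the fixed keratinocyte and epithelial markers, CLDN4 rose 7.97-fold and KRT14 7.23-fold beside this group, while EPCAM, CDH1, KRT5 and KRT19 were at 0.332 FPKM or less in the mean of each group. FOXO target genes rose in 7 of 18 cases and fell in 0, with a median of 0.42 (camera adjusted p = 3.40e-05; adjusted p = 0.0358 with an estimated correlation). KLF7 rose from 6.60 to 22.2 FPKM, PINK1, a kinase of mitochondrial quality control, from 37.0 to 94.8 FPKM and CCNG2, a cyclin of cell cycle arrest, from 6.44 to 12.7 FPKM.

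Genes of ribosome biogenesis fell in 20 of 27 cases and rose in 0, with a median of -0.59 (camera adjusted p = 2.02e-09; adjusted p = 0.0373 with an estimated correlation). NOP56, a core protein of box C/D snoRNPs, fell from 248.1 ± 1.77 to 128.9 ± 7.45 FPKM and WDR12, of pre-60S maturation, from 119.9 to 75.3 FPKM. Of 54 replication-dependent histone genes 14 fell, 0 rose and the median was -0.21 (camera adjusted p = 3.40e-05), but their adjusted p was 0.338 with an estimated correlation, and since histone mRNAs mostly lack a poly(A) tail and the RNA selection is not given in the sources used here, their values may also depend on how the libraries were made.

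The real grouping of the 6 libraries gave 3971 changed genes, and the highest of the 9 other splits gave 7, while for lists the real grouping gave 14 and the highest other split 10. In both cases 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05.

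More genes were above 0 after fluvastatin, 24030 ± 103 (SD, n = 3) against 22585 ± 333 in the controls. Thinning the genes resolved to whole fragments to the shallowest library brought the difference of the means from 962 down to 388, against a larger SD of 249 within a group, and fluvastatin replicate 2 at 2779 then lay below control replicate 2 at 2826. The fragment numbers were the smallest that the values allowed, and too low a number makes thinning remove too many detections from deeper libraries. Among the resolved genes, the only ones thinned, depth may thus account for some or most of the difference. Fragments of genomic DNA or unspliced RNA could add to it, but the ratio of detections of 71 olfactory receptor genes, silent in most tissues, was 1.16 (95% interval 0.79 to 1.64) beside 1.15 for all resolved genes, which leaves that open. At equal depth the ratio was 1.38 for protein-coding genes and 1.01 for processed pseudogenes, and a biological gain of transcripts was not tested apart from these.

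Of the 499 genes changed at least 2-fold, 27 were under 300 nt, among them 11 of the 24 largest changes. Reads of an overlapping longer gene that changed the same way could account for only 18.5% of them (5 of 27). The few fragments behind each value remain a candidate explanation. By the smallest numbers that the values allow, the median gene of this kind had 4.0 fragments in its highest library. Of the 22 resolved ones, 18 had at most 5, and the true numbers may be higher. MIR4263, for example, was listed at 0 in all controls and reached 32.7, 27.5 and 29.6 FPKM in fluvastatin replicates 0, 1 and 2. These values can come from as few as 1 fragment in each. RNY3 and MIR3936 lost their calls in 9 and 10 alternatives, among them no filter on low values, at adjusted p = 0.105 and 0.138, over ranges of 0.0133 to 0.385 and 0.00751 to 0.290.

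PTPRD was listed at 0 in all 3 fluvastatin libraries, where the control mean would correspond to 8344, 9576 and 8709 fragments in replicates 0, 1 and 2, and 0 of the 5 features within the locus were above 0 there, against 5 in at least 1 control. RP11-134K1.2 and RN7SL5P were above 0 in only 1 control each, and RP11-134K1.3 reached at most 0.382 FPKM, so the pattern rests on PTPRD and PTPRD-AS1. PTPRD-AS2, just past the locus, was at 0 in all controls and at 0.0168 and 0.0197 FPKM in fluvastatin replicates 1 and 2. Zeros arising independently in single libraries, at 1 rate for all genes, are argued against, since 1.5e-07 genes would then be at 0 in all 3 libraries of 1 group. Among other genes with at least 100 expected fragments, however, some zeros recurred, as for RP11-203J24.9 in control replicates 0 and 2. The 1.5e-07 thus does not cover failures that recur at the same gene. Treated cells from a clone differing in whole chromosomes are argued against as well, since the largest shift of a chromosome median was 0.065 and 29 of 100 shuffles gave as much. A clone with wider copy-number differences stays open, with an SD of 0.083 over windows of 30 genes, which 2 of 100 shuffles reached. An estimate that failed at certain loci may also be the cause, as 13 of 69873 other gene and library pairs with at least 100 expected fragments were at 0. Some of these pairs were of short genes, such as ZNFX1-AS1_3 (87 nt) and NEAT1_1 (120 nt). The expected fragments of short genes are uncertain, so their zeros may come from few fragments. Others were of longer genes, such as MN1 (7556 nt) and DNAJC27-AS1 (4660 nt). A loss of the locus from the treated cells and a failed estimate in all 3 treated libraries cannot be told apart, because both leave 0 features above 0 and no reads were analysed here.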
